A study of Sus scrofa with 2 samples.

How the data were processed

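Small RNA libraries were made from total RNA of pig oocytes by adapter ligation, reverse transcription and PCR, and sequenced on an Illumina instrument, per the labels' protocols. The authors deposited 1 table per library, which lists each distinct sequence with its length and its raw read count, and the count is not normalized. Bowtie2 is named in the submitters' processing notes. Its version, the genome build and the trimming settings were not given in the sources used here. The tables hold sequences of 18 to 44 nt and keep sequences with a single read, 394582 in the control library and 349389 in the knockdown library. In the control library 63.0% of the reads longer than 40 nt still held the start of the 3' adapter, and in the knockdown library 62.9%. Reads longer than 32 nt were 0.209% and 0.260% of the total, and 3 knockdown sequences contained an undetermined base.

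No genome was used here, so sequences were not placed on chromosomes and no coordinates are given. Sequences were matched to 172 conserved mature miRNAs, a SINE1 consensus of 257 nt, 11 tRNAs, 5S and 5.8S rRNA, U6 and the Y RNAs Y1, Y3 and Y4. These references were written by hand from background knowledge of vertebrate RNAs before the data were examined. Pig-specific miRNAs are therefore not counted. A read was assigned to a miRNA when it held nt 2 to 20 of the mature sequence, began within 2 nt of its 5' end and was 19 to 26 nt long. miR-103 and miR-107, and miR-17-5p and miR-106a, share that stretch and were counted together, which left 170 entries. Other classes needed an exact match on the sense strand, and SINE1 an exact match on either strand, with assignment in the order miRNA, tRNA, rRNA, snRNA or Y RNA, SINE1, other. Exact SINE1 matches covered 221 of the consensus positions, and the reversed consensus, used as a decoy, had 0 matches with up to 2 mismatches. The SINE1 subfamily was not resolved. Segments of 18S and 28S rRNA and of Y5 were added after the values had been seen, to identify abundant sequences.

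RPM values are reads of an item scaled to all reads of its library. Shares have exact (Clopper-Pearson) binomial intervals, counts exact Poisson intervals and ratios exact conditional intervals, all at 95%. A count of 0 was set to a floor of 3 reads, worth 0.253 RPM in the control library and 0.250 RPM in the knockdown library. Log2 ratios of single miRNAs had 0.5 reads added to each count. With 1 library per group no p-value was computed. A miRNA counted as detected with at least 10 reads in both libraries together, and as changed with at least 100 reads and a ratio of at least 2 or at most 0.5. The median of each miRNA list was placed among 10000 random lists of unmatched sequences of 19 to 26 nt, matched on abundance, as a description of these libraries. The duplex score counts pairs of reads of 21 to 23 nt on opposite strands of the consensus. It compares overlaps of the 5' ends that are 2 nt shorter than these lengths with all other overlaps up to 30 nt. Read lengths are pooled, so a counted pair of unlike lengths need not leave 2-nt overhangs at both ends. Scores by length use reads of 1 length only.

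Named miRNAs were the 12 most abundant, the 6 with the largest ratio in each direction among those changed, the detected let-7 members, miR-21-5p, miR-451, miR-202-5p and miR-16. Named sequences were taken from the 5 most abundant, the 5 with the largest ratio in each direction among those with at least 1000 reads, and the 3 most abundant SINE1 matches of 21 to 23 nt per strand. The 2-fold rule and the intervals were tested on simulated counts for the 13652 sequences with at least 100 reads. All 164 sequences changed 4-fold that kept 100 reads were recovered, 0 unchanged ones were called, and 95.6% of intervals held the true value. These counts were drawn with Poisson error alone, so the simulation checks the calculation. It cannot show how often replicate libraries would differ by 2-fold. Planted duplexes gave a z-score of 19.7 and randomly placed reads 0.941, at a planted depth that was not matched to these libraries. Alternatives covered the reads that values are relative to, rare sequences, length windows, mismatches, the miRNA match and read minimums. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.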

Results

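Small RNA was sequenced from pig oocytes that had matured in vitro for 42 h and stood at metaphase II, the stage at which an oocyte is ready for fertilisation. The 2 libraries were a control and oocytes in which Dicer, the ribonuclease that cuts hairpins and double-stranded RNA into miRNAs and siRNAs, had been knocked down with siRNA at the germinal vesicle stage, before maturation. There was 1 library per group, so no test between groups was possible and every comparison below is between these libraries, not between the conditions. The control library held 11836160 reads of 720572 distinct sequences and the knockdown library 11982925 reads of 689709 distinct sequences. Intervals are 95% intervals and cover counting error only, because PCR reads without molecular identifiers are not independent molecules. The level of the Dicer transcript itself was not measured by these small RNA libraries and was not analysed here. Whether Dicer was lower in the oocytes labelled as knockdown is therefore not known from these libraries.

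Both libraries were dominated by RNAs of 22 to 24 nt and of 27 to 28 nt that began with T, and their most abundant sequences were shared. The sequence TTCTGTAGCAACAGTTAAAACGACCCT, of 27 nt, took 5.65% of the control reads and 5.70% of the knockdown reads. The 28-nt sequence TTCTGCTTGAGTTGTAGCTGTTATGCCT was likewise at nearly equal levels, with a ratio of knockdown to control of 0.996 (interval 0.992 to 1.001). TTACTTTCCAGTCTGTGGGGCTT, of 23 nt, was higher in the knockdown library, with a ratio of 1.31 (1.30 to 1.32). Another of the 5 most abundant sequences was the full mature form of miR-10b, TACCCTGTAGAACCGAATTTGT, with 318321 and 323333 reads. Sequences seen in both libraries made up 20.9% of the 1166705 distinct sequences but 93.9% of control reads and 94.0% of knockdown reads. Of the 1853 sequences with at least 1000 reads in both libraries together, 1707 differed by less than 2-fold, 86 were at least 2-fold higher in the knockdown library and 60 at least 2-fold lower.

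The first comparison asked whether RNAs of the size that Dicer makes were depleted. Reads that matched none of the references used here made up 91.1% of control reads and 90.7% of knockdown reads. Most reads of this size were therefore of unknown origin, so their share could miss a loss of Dicer products. Reads of 21 to 23 nt made up 35.2% of the control library (exact binomial interval 35.1 to 35.2%) and 33.3% of the knockdown library (33.3 to 33.4%), a ratio of 0.948 (0.947 to 0.949). Reads of 24 to 32 nt, a range that holds piRNAs, the small RNAs that guide Piwi proteins in germ cells, made up 61.2% (61.2 to 61.2%) and 62.8% (62.8 to 62.9%), a ratio of 1.03 (1.03 to 1.03). Reads of 22 nt were at 11.1% and 10.3%, and reads of 29 nt at 4.12% and 4.95%. The 24-nt reads, above the size class of Dicer products, were lower by about as much as those of 22 and 23 nt, with a log2 ratio of -0.08 against -0.11 and -0.06. Reads of tRNA, rRNA, snRNA and Y RNA together were 1.18-fold higher in the knockdown library. Measured against them, the class of 24 to 32 nt was also lower in the knockdown library, with a log2 ratio of -0.21. T was the first base of 85.5% of the reads of 24 to 32 nt that matched no miRNA in the control library and 84.5% in the knockdown library, and of 87.1% and 85.1% of those of 21 to 23 nt.

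**Figure D1:**
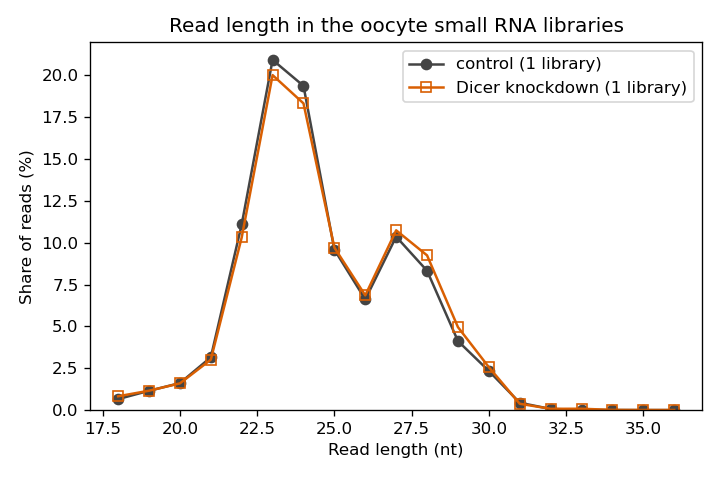
Share of reads (%, vertical axis) at each read length (nt, horizontal axis) in the control library and the Dicer knockdown library, 1 point per length. Both libraries peaked at 23 nt, with 20.9% and 20.01% of reads, and again at 27 nt, with 10.4% and 10.7%.

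Conserved miRNAs took nearly the same share of both libraries. They held 6.49% of control reads (6.47 to 6.50%) and 6.47% of knockdown reads (6.46 to 6.48%), a ratio of 0.997 (0.994 to 1.0005), so the difference was within counting error. The sign of this difference depended on what was counted, with a log2 ratio of -0.0039 for all reads, 0.0470 without the 10 most abundant sequences and -0.249 relative to tRNA, rRNA, snRNA and Y RNA. Of the 74 miRNAs with at least 100 reads, 14 were at least 2-fold higher in the knockdown library, 1 was at least 2-fold lower and 59 were neither. The median log2 ratio over the 117 detected miRNAs was 0.26, above all 10000 random lists of other sequences of 19 to 26 nt matched on abundance, whose central 95% ran from -0.23 to 0.01. Against tRNA, rRNA, snRNA and Y RNA reads the median was 0.02, with 10 miRNAs higher and 4 lower by 2-fold or more.

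A pair of miRNAs dominated, miR-10b at nearly equal levels and miR-182 slightly lower in the knockdown library. miR-10b, encoded within a Hox gene cluster, was at 35725 RPM (read counts scaled to equal library size) in the control library and 36180 RPM in the knockdown library, a ratio of 1.01 (1.01 to 1.02). miR-182, a member of the miR-183 cluster, was at 18393 and 16217 RPM, a ratio of 0.882 (0.876 to 0.887). Together they held 83.4% of control miRNA reads and 81.0% of knockdown miRNA reads. miR-148a stood at 2831 and 2945 RPM, miR-128 at 367 and 382 RPM and let-7a at 372 and 397 RPM. miR-205 was lower in the knockdown library, with a ratio of 0.816 (0.800 to 0.832), as was miR-92a, with 0.907 (0.884 to 0.930). let-7f, miR-30a and miR-21-5p were higher, with ratios of 1.27 (1.24 to 1.31), 1.27 (1.22 to 1.31) and 1.29 (1.25 to 1.34).

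Among the 74 miRNAs with at least 100 reads, the largest ratio was that of miR-130a, with 9 control reads and 334 knockdown reads, a ratio of 36.7 (19.1 to 80.9). Its knockdown reads were mostly a 20-nt form, CAGTGCAATGTTAAAAGGGC, with 286 reads, and the full 22-nt form had 17. miR-378 followed with a ratio of 6.25 (4.61 to 8.63), then miR-143, abundant in smooth muscle and stromal cells, with 4.92 (4.32 to 5.63). miR-27b was 4.45-fold higher (4.19 to 4.74), miR-140-3p, known from cartilage, 3.20-fold (2.85 to 3.60) and miR-10a 3.13-fold (2.73 to 3.59). miR-423-5p, also among the 12 most abundant, was 3.09-fold higher (2.95 to 3.23). miR-100 was the 1 of these 74 miRNAs at least 2-fold lower, at 178 RPM in the control library and 55.2 RPM in the knockdown library, 3.23-fold lower (2.96 to 3.54).

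**Figure D2:**
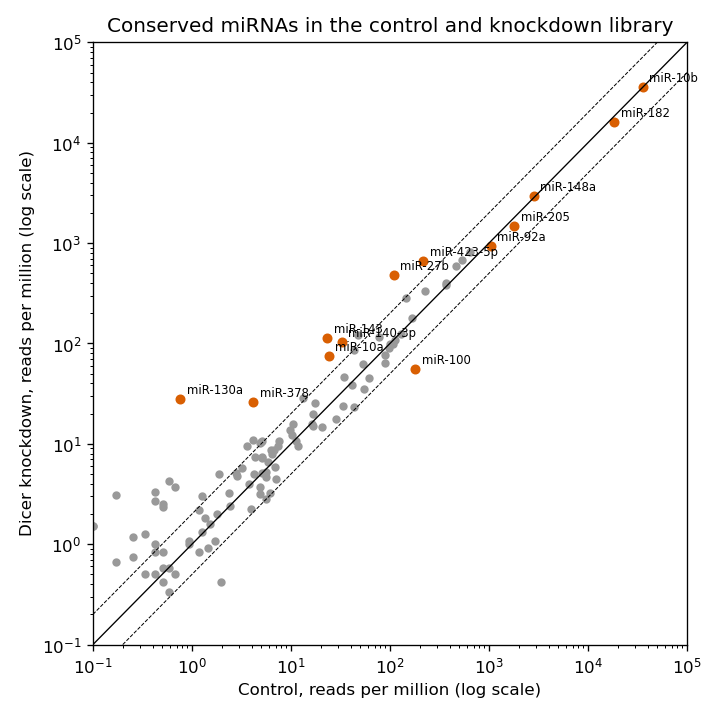
Each point is 1 conserved miRNA with at least 10 reads, placed by its RPM in the control library (horizontal, log scale) and the Dicer knockdown library (vertical, log scale); values under 0.1 are drawn at 0.1, the solid line marks equality and the dashed lines a 2-fold difference. miR-10b and miR-182 lie near equality, miR-130a lies 36.7-fold above it and miR-100 3.23-fold below it.

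By miRNA family, all 9 let-7 members differed by less than 2-fold. The let-7 median log2 ratio was 0.27, at percentile 97.52 of random lists of other sequences and close to the 0.26 of all detected miRNAs, and values ran from 1.66 for let-7b (1.06 to 2.61) to 0.918 for let-7i (0.847 to 0.995) as ratios. let-7e had a ratio of 1.45 (1.21 to 1.73), let-7c 1.501 (1.19 to 1.90), miR-98 1.21 (0.883 to 1.65), let-7d 1.19 (0.801 to 1.76) and let-7g 0.951 (0.740 to 1.22). The 5 miR-30 members had a median of 0.34, at percentile 96.3, with 1 of them 2-fold higher. In the list of miR-10, miR-99, miR-100 and miR-125 forms, 2 of 7 members were 2-fold higher and 1 lower, with a median of 0.02. The miR-17/92 list had a median of -0.12 over 7 detected members and the miR-15/16 list 0.11 over 4. miR-16 itself had a ratio of 0.870 (0.796 to 0.952). The epithelial list, which holds miR-182 and miR-205, had a median of -0.22 over 7 members, at percentile 24.9.

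Of the lists that mark other cell types, the stromal list alone had a median outside the central 95% of random lists. The stromal list summed to 27.6 RPM in the control library and 124 RPM in the knockdown library, a ratio of 4.49 (3.98 to 5.08), and its 3 detected members, miR-143, miR-199a-3p and miR-126-5p, had a median log2 ratio of 2.30, at percentile 99.9. miR-143 alone held 275 of the 327 control reads and 1371 of the 1487 knockdown reads of this list, and the median is its own value. The granulosa list had a median of 0.19 over 5 members, at percentile 80.5. miR-202-5p, a gonadal miRNA on that list, had 6 control and 28 knockdown reads, a ratio of 4.61 (1.87 to 13.6). Its other detected members went in both directions, with 1.29 for miR-21-5p and 1.15 for miR-212. miR-383 had a ratio of 0.567 (0.340 to 0.930), on 47 and 27 reads, and miR-132 0.762 (0.503 to 1.15). The blood list had a median of 0.93 over 2 members, at percentile 91.4. The muscle list had 1 detected member, with a log2 ratio of -0.62, and the imprinted list 1, with 0.51. No read matched the 5 miRNAs of the pluripotent embryo list in either library. miR-451, which matures without Dicer, had 7 control and 4 knockdown reads, a ratio of 0.564 (0.121 to 2.22), so a difference was not detectable at this depth.

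The title of the series names SINE1B, a pig retroposon, as a target of endogenous siRNAs, so reads matching the SINE1 family were counted on both strands of a consensus. SINE1-matching reads of 21 to 23 nt were higher, not lower, in the knockdown library, at 38.8 RPM (exact Poisson interval 35.3 to 42.5) in the control library and 70.4 RPM (65.8 to 75.4) in the knockdown library, a ratio of 1.82 (1.62 to 2.04). Sense reads went from 411 to 592 and antisense reads from 48 to 252, so that the antisense ratio was 5.19 (3.80 to 7.22) for exact matches. It fell to 1.99 (1.84 to 2.16) with 1 mismatch, on 947 and 1912 reads, and to 1.29 (1.24 to 1.35) with 2, on 3996 and 5238 reads. The antisense share was 10.5% (exact binomial interval 7.81 to 13.6%) in the control library and 29.9% (26.8 to 33.1%) in the knockdown library. With up to 2 mismatches, which took in 10731 and 12597 reads, the log2 ratio of the total was 0.21 and the shares were 37.2% and 41.6%.

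The most abundant sense sequence of this size, GGTTAACGAATCCGACTAGGAAC at positions 23 to 45 of the consensus, had 113 control and 185 knockdown reads, a ratio of 1.62 (1.27 to 2.06). TTCCCGTCGTGGCGCAGTGGTT had 22 and 25 reads and TTAACGAATCCGACTAGGAACC 16 and 18. On the antisense strand TCGGATTCGTTAACCACTGCGCC, at positions 15 to 37, had 4 and 57 reads, a ratio of 14.1 (5.21 to 53.4). TCGAATCGGAGCTGTAGCCGCC had 23 and 12 reads, a ratio of 0.515 (0.234 to 1.08). ATCGGAGCTGTAGCCGCCGGCC had 0 and 24, at least 7.90-fold higher against a floor of 3 reads and at least 5.95-fold by the exact interval.

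**Figure D3:**
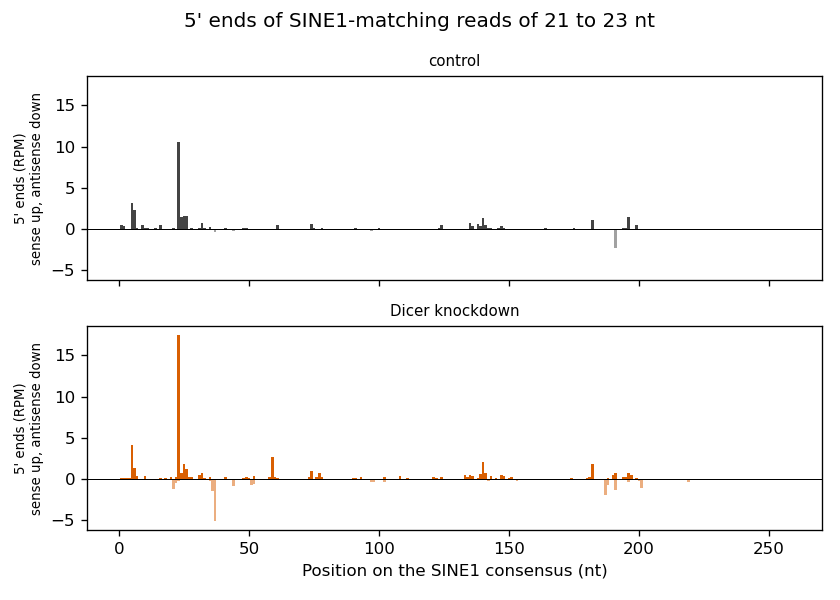
RPM of reads whose 5' end lies at each position of the SINE1 consensus (nt, horizontal axis), for reads of 21 to 23 nt in the control library and the Dicer knockdown library, with sense reads above 0 and antisense reads below it. The sense peak at position 23 is in both libraries, and antisense reads with a 5' end at position 37 stand out in the knockdown library.

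Pairs of sense and antisense reads with the 2-nt 3' overhangs of a Dicer duplex were compared with pairs at other overlaps. The duplex z-score over overlaps of 1 to 30 nt, for exact matches of 21 to 23 nt together, was 0.982 in the control library and 0.695 in the knockdown library, and with 1 mismatch 1.57 and 1.56. By length, exact matches gave 3.24 and 1.34 for 21 nt, on 3 and 7 pairs, 1.85 and 0.834 for 22 nt and 0.670 and 0.575 for 23 nt. With 1 mismatch the scores were 2.28 and 2.13 for 21 nt, on 55 and 82 pairs, 1.27 and 2.17 for 22 nt and 0.751 and 1.54 for 23 nt. For exact matches of 21 to 23 nt with each distinct sequence counted once, the scores were 1.59 and 2.58, and with 1 mismatch 1.36 and 2.30. For the 10-nt overlap that marks the piRNA ping-pong cycle, reads of 24 to 32 nt gave a z-score of 6.54 on 28 pairs in the control library and 0.150 on 29 pairs in the knockdown library. With 1 mismatch allowed the 10-nt overlap was the most frequent in both libraries, with z-scores of 7.93 and 6.78. When each distinct sequence was counted once, the z-scores of this overlap were 3.80 and -0.566 for exact matches and 5.31 and 1.95 with 1 mismatch. Among reads of 21 to 23 nt, 10 nt was also the most frequent overlap in the control library, with 20 pairs for exact matches and 189 with 1 mismatch. In the knockdown library the most frequent overlaps of that size were 15 nt and 6 nt by reads. With each distinct sequence counted once it was 21 nt, a scored overlap, with 26 pairs for exact matches and 153 with 1 mismatch. By length, distinct sequences with 1 mismatch gave control and knockdown scores of 2.11 and 3.62 for 21 nt. They gave 0.492 and 0.733 for 22 nt and 1.18 and 3.23 for 23 nt. For exact matches these scores were 2.49 and 2.02, 0.816 and -0.179, and 1.33 and 0.813. The duplex score counts pairs at 10, 15 and 6 nt among the other overlaps.

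Among other RNA classes, fragments of Y RNA, small cytoplasmic RNAs bound by the Ro protein, differed most. Y4 fragments went from 919 to 5168 reads, a ratio of 5.55 (5.18 to 5.96), Y1 fragments from 68 to 355 and Y3 fragments from 172 to 377. Fragments of 5S rRNA had a ratio of 1.16 (1.15 to 1.16) and of 5.8S rRNA 1.21 (1.20 to 1.23). tRNA fragments went in both directions. Those of tRNA Glu-TTC were higher, with 255 and 952 reads, and those of His-GTG too, with 4029 and 5888. Those of Gly-GCC, with 1295 and 865 reads, and Leu-CAG, with 1139 and 825, were lower. These are exact matches only, which leaves out fragments with mismatches. A 3' fragment 1 mismatch from Gly-GCC had 5520 control and 1238 knockdown reads, and another, with 2 mismatches, 2906 and 671. The exact counts may therefore understate how much lower Gly-GCC fragments were. The tRNA class totals were not repeated with mismatches allowed. U6 had 26 and 21 reads.

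The sequences with the largest ratios were rich in G and C. TCCCGCCCGTCGCCCGCGCG had 11 control and 5049 knockdown reads, a ratio of 453 (253 to 909). CGGCGGCGGCGACTCTGGACGC, with 27 and 6386 reads, and its extension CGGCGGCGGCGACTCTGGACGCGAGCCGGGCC, with 6 and 1416, held runs of 18 and 28 nt of 28S rRNA. GGCCCTGGCGGAGCGCTGAGAAGACGGTC, with 4 and 1824 reads, and CGGCCCTGGCGGAGCGCTGAGAAGACGGTC, with 3 and 1095, each held a run of 27 nt of another added rRNA segment. Whether that segment is 18S or 28S rRNA was not checked against pig sequences. In the other direction, TACAGTGGCTGTGGCTCGACCCC had 1583 reads in the control library and 0 in the knockdown library, at least 534-fold lower against a floor of 3 reads and at least 434-fold by the exact interval. Its shorter forms TACAGTGGCTGTGGCTCGACCC and TACAGTGGCTGTGGCTCGACC had 1489 and 1046 control reads and 0 knockdown reads, at least 502-fold and 353-fold lower against the floor and at least 408-fold and 287-fold by the exact interval. TCGTTTCCCGGCCCATGCACCA, 1 mismatch from the 3' end of tRNA Gly-GCC, was 4.51-fold lower (4.24 to 4.80), and TCGTTTCCCGGCCAATGCACCA, with 2 mismatches, was 4.38-fold lower (4.03 to 4.78).

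**Figure D4:**
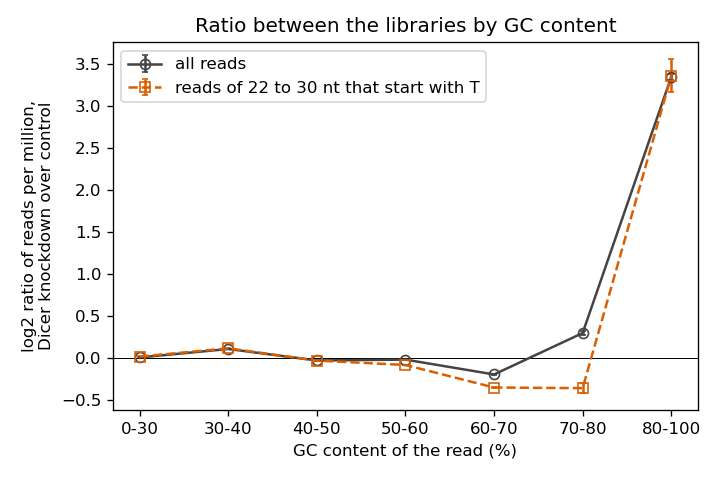
The log2 ratio of RPM, Dicer knockdown over control (vertical axis), for reads grouped by GC content (%, horizontal axis), with 95% counting intervals as bars, for all reads and for reads of 22 to 30 nt that start with T. All reads lie at a log2 ratio of 0.29 for 70 to 80% GC and 3.35 for at least 80%, and reads that start with T at -0.36 and 3.36.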

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

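Signals outside the main measurements stood above the control library in 3 places. The tests of lengths that Dicer does not make, of GC content among reads starting with T and of the stromal and granulosa lists were chosen after the values had been seen. So were the sequences and miRNAs named here outside the naming rule.

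Forms of the listed miRNAs cut to 18 nt, too short to be counted as miRNAs, were 4.42-fold higher in the knockdown library (4.14 to 4.73), with 1048 and 4693 reads, against 1.21-fold for other 18-nt reads. miR-10b contributed 391 and 2687 of these reads, and the form shared by miR-103 and miR-107 had 30 and 1109, while the 20 to 26 nt forms of that pair had 732 and 555. Without these forms the ratio was 1.41 (1.27 to 1.57), with 627 and 897 reads. The 18-nt form of miR-182 went the other way, with 379 and 303 reads.

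Reads of 33 to 40 nt, outside both length classes, were 3.76-fold higher (3.61 to 3.91), with 3061 and 11643 reads. A single 33-nt sequence with 28S rRNA sequence, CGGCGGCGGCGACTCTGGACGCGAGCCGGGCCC, had 34 and 7462 of them.

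Reads with at least 80% GC were 10.2-fold higher in the knockdown library (9.95 to 10.4), with 7208 and 74350 reads, and Y RNA fragments were higher too. A gradual GC bias runs against 2 values: reads of 22 to 30 nt starting with T and with 70 to 80% GC were lower, with a ratio of 0.778 (0.745 to 0.812), and Y RNA reads with less than 50% GC were 13.0-fold higher (10.7 to 16.02), but all reads with 70 to 80% GC were 1.23-fold higher (1.21 to 1.24) and those starting with T and with at least 80% GC 10.3-fold (8.97 to 11.8), so a bias that acts at high GC alone stays open for the GC-rich reads. RNA of other cells in the knockdown pool may contribute, since the 3 detected stromal miRNAs had a median log2 ratio of 2.30, the value of miR-143 itself, outside the range of random lists (-0.95 to 0.83), although 3 of the 7 listed members also had control reads and miR-143, which held most of the list's reads, reached only 114 RPM. For cumulus or granulosa cells the median was 0.19, within the range of random lists, so this source cannot be told apart from none. RNA breakdown after Dicer knockdown stays open as an untested biological explanation, since each condition has 1 library.

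Antisense SINE1 reads of 21 to 23 nt were 5.19-fold higher in the knockdown library for exact matches, 1.99-fold with 1 mismatch and 1.29-fold with 2, against the loss that siRNAs made by Dicer would show. Without the 5 most abundant antisense sequences the ratio was 6.02 (3.78 to 10.1), on 21 and 128 reads. These 5 included 1 that went the other way, with 23 control and 12 knockdown reads. The rise from 5.19 therefore does not show that the abundant sequences contributed nothing, and their part was not measured. Among antisense reads with less than 60% GC the ratio was 7.84 (4.65 to 14.1). Both values argue against a few sequences or GC-rich fragments as the whole cause. Antisense reads of 24 to 32 nt were also higher, 3.16-fold (2.28 to 4.46) for exact matches, on 49 and 157 reads. This ratio fell to 1.61 (1.45 to 1.80) with 1 mismatch and to 1.13 (1.10 to 1.17) with 2. A higher level of longer antisense fragments may therefore account for part of the difference. Exact antisense matches of 18 to 20 nt did not differ beyond counting error, with a ratio of 0.985 (0.841 to 1.15). With 1 and 2 mismatches those of 18 to 20 nt were higher too, at 1.14 (1.08 to 1.21) and 1.25 (1.19 to 1.31). An effect of Dicer knockdown on the retroposon stays open and was not tested, since each condition has 1 library.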

How the results depend on the processing

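Of 51 alternatives, 26 left the value within its interval, or a count within 1.5-fold, 23 moved it and 2 reversed its sign. All values here are log2 ratios of knockdown to control unless named otherwise. Relative to tRNA, rRNA, snRNA and Y RNA reads, each log2 ratio fell by the same 0.245. That is the log2 ratio of those reads themselves, which were 1.18-fold higher in the knockdown library. These shifts are therefore 1 common offset. The cause of the other changes was not tested.

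The miRNA share, at -0.0039, turned to 0.0470 without the 10 most abundant sequences, and was -0.249 relative to tRNA, rRNA, snRNA and Y RNA reads, -0.0101 without single-read sequences and -0.0093 for full mature sequences. The share of 21 to 23 nt, at -0.08, was -0.111 without the 10 most abundant sequences, -0.0922 among reads matching no miRNA, -0.322 relative to tRNA, rRNA, snRNA and Y RNA, and -0.105 for 22 nt alone. The share of 24 to 32 nt, at 0.04, was 0.0393 among reads of 18 to 30 nt, 0.0482 without the 10 most abundant sequences, 0.0416 among reads matching no miRNA and 0.110 for 26 to 32 nt, and turned to -0.207 relative to tRNA, rRNA, snRNA and Y RNA.

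SINE1 reads of 21 to 23 nt, at 0.86, were 0.62 relative to tRNA, rRNA, snRNA and Y RNA, 0.55 for 20 to 24 nt, 0.47 with 1 mismatch and 0.21 with 2. The antisense share, 19.4 percentage points higher in the knockdown library, was 14.5 points higher with 1 mismatch, 4.34 with 2 and 13.0 for 20 to 24 nt. The miRNA median of 0.26 was 0.0171 relative to tRNA, rRNA, snRNA and Y RNA, with an interval of -0.0373 to 0.138 that includes 0. The number of changed miRNAs, 15, was 32 with a minimum of 10 reads, 7 with 1000 and 10 for full mature sequences. The duplex z-score of the knockdown library, 0.695, was 1.56 with 1 mismatch and 2.58 for distinct sequences. The direction of the SINE1 read ratio, of the antisense share and of the share of 21 to 23 nt held under every alternative run. The planned count over genomic SINE1 copies was not run, as no genome was used here. No paired analysis was possible because each group has 1 library.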

Other observations

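The tests of an injected duplex and the search for families found in 1 library were made after the sequences had been seen. Sequences named here outside the naming rule were chosen after their values had been seen.

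Some tRNA 3' fragments differed from the coded base, those of Gly-GCC most often at 1 position of the T loop. The 22-nt 3' fragment of tRNA Gly-GCC, TCGATTCCCGGCCCATGCACCA, was read as coded in 397 control and 119 knockdown reads, while the form with the substitution A4T, counted from 1 at the fragment's 5' end, had 5520 and 1238. Bases other than A at this position, which in many tRNAs is 1-methyladenosine, a base that reverse transcriptase misreads, took 93.3% of these control reads (92.6 to 93.9%) and 91.3% of knockdown reads (89.6 to 92.7%). For Gly-CCC the shares were 78.3% and 76.5%. They were lower for Leu-CAG, at 19.5% and 32.4%, and for Val-CAC, at 5.60% and 11.2%. Both Gly-GCC forms were more abundant in the control library, and a gene variant with that base was not excluded. Both libraries also had reads that differed at other positions, in the control library 482 at position 14 of Gly-GCC, 174 at position 13 of Leu-CAG, 134 at position 6 of Val-CAC and 28 at position 5 of His-GTG.

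Among distinct sequences of 24 to 32 nt that matched no miRNA and did not begin with T, A stood at position 10 in 32.5% of control and 32.2% of knockdown sequences, against 28.1% and 28.02% at position 9 and 28.3% and 28.1% at position 11. This preference is a trait of secondary piRNAs. Searched without any reference, 22-nt reads that pair with another 22-nt read to leave 2-nt overhangs came to 3494 RPM in the control library and 547 RPM in the knockdown library. Once the most abundant sequence of each library was left out these were 449 and 425 RPM. On the same count 5-nt overhangs gave 471 and 431 RPM, and overhangs of 0, 1, 3 and 4 nt gave 71.3 to 235 RPM. At 21 and 23 nt, counted in the same way, 2-nt overhangs did not stand out. Reads of 23 nt gave 296 and 321 RPM with 2-nt overhangs but 508 and 640 RPM with 3-nt ones. Reads of 21 nt gave 108 and 94.1 RPM with 2-nt overhangs but 149 and 117 RPM with 4-nt ones.

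Some sequence families were found in 1 library. Sequences with the stretch GTGGCTGTGGCTCGA had 9172 control reads in 309 forms and 5 knockdown reads. Those with ACCCCTGGCCTGGGAACTTCC, 2 mismatches from the SINE1 consensus, had 1 control and 1167 knockdown reads. In the control-only family 37.6% of reads (36.6 to 38.6%) were longer than 23 nt, which argues against an injected duplex. For the members of each family with at least 200 reads in 1 library and 0 in the other, sequences 1 base away had, in that other library, 1.59% of the reads of the control-only members and 0.0948% of those of the knockdown-only members, which argues against a single-base variant between the oocyte pools. A locus present in the animals of 1 pool and absent from the other, or active in it alone, is a hypothesis that could not be tested without a genome.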
